A study of Mus musculus with 10 samples.

How the data were processed

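Total RNA of 10 MEF samples (1 microgram each, RNA integrity number of at least 7.0) was turned into digoxigenin-labelled cRNA and hybridized to 1-colour Applied Biosystems mouse arrays of 33012 probes, per the labels' protocols. For each array the authors deposited a signal intensity per probe, a signal-to-noise score, a flag and a normalized intensity. The scanner software, the background correction and the meaning of the flags are not given in the sources used here. The deposited normalized intensities have the same sorted values on all Ad-Cre arrays (within 0.287%) and on all Cre-ER arrays (within 0.562%), but differ by a median of 29.7% between the systems. They equal the mean of the sorted signals within 0.0937%. From these values, the authors' normalization was quantile normalization within each system alone, so its levels cannot be compared between the systems. The unnormalized signal intensity was therefore used. The series table holds the same normalized intensities (largest difference 0) and was an alternative.

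The signals were quantile normalized over the 10 arrays with limma 3.58.1 in R 4.3.3, raised to a floor of 857.06 (9.74 on the log2 scale), the median over arrays of the 5th percentile of detected probes, and taken to log2. A probe was detected on an array with a signal-to-noise score of at least 3 and a flag of at most 5000, and spots with a higher flag were left out (311 among the tested probes), a limit set once the flags were seen. Tested were the 19323 probes (58.5%) detected on at least 2 arrays. Of these, 12857 lay above the floor on all arrays and 619 on none. Per array, 44.9% to 52.71% of the probes were detected. Changes of dim genes are understated. The SE of a gene at the floor in any group, also one outside the comparison, is too small. Arrays at the floor carry no spread, and all groups share 1 estimate of it. Where a gene named for a comparison was not detected on any array of a group, or lay at the floor on all of them, the fold is given as "at least" or the value is called a bound, with the floor, or the dim probe's own value where that is higher, as the level of the dim group. Gene names came from the platform annotation: 14411 probes had 1 symbol, 247 several and 18354 none here, and 14402 of the symbols were found by their Entrez number in a RefSeq gene table, which changed 0 of them. Of the tested probes, 52.8% had 1 symbol, for 9843 genes. For named genes and lists, a gene is its probe with the highest mean. Other probes were looked at, and Cebpb, Stard4, Idi1 and Psat1, which have 1 more each, did not change direction in the comparisons named.

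A linear model with a mean for each of the 5 groups and an additive 72 h term for the Ad-Cre arrays was fitted to all 10 arrays with limma (lmFit and eBayes), leaving 4 residual degrees of freedom, so that all groups share 1 estimate of the spread. Compared were Ad-Cre Fl/- with Fl/+, the mean of both 4OHT groups with vehicle, each 4OHT group with vehicle, 72 h with 64 h in each system, and the Ad-Cre difference with the 4OHT difference. P-values are two-sided and adjusted by Benjamini-Hochberg over the probes of each comparison. A probe was called at an adjusted p under 0.05. The labels do not say whether the 2 Ad-Cre arrays of a genotype came from separate cultures, so the Ad-Cre arrays may add only technical spread. Most of the residual degrees of freedom come from the Cre-ER arrays, so the Ad-Cre p-values rest largely on the spread of the other system. For Rpl39l the SD was 0.0101 and 0.268 in the Ad-Cre groups and 0.844 to 1.15 in the Cre-ER groups. For the Cre-ER arrays, the replicate number is the MEF preparation, per the series design. Deviations from the group means correlated across probes with r = 0.163, 0.204 and 0.267 between same-numbered arrays of the 3 group pairs. The main model had no block, and a fit with the preparation as a block was run beside it: it called 0 probes after 4OHT against 4 in the main model. The fits were tested on simulated data of 19045 probes first. Changes were set only in probes well above the floor, and all arrays were drawn independently, without the correlation within a preparation. In the Ad-Cre layout 46% of probes changed 2-fold and 94% of those changed 4-fold were found with 11 false calls, and in the 4OHT layout 74% and 95% with 15.

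Before the data were examined, the tests, the gene lists and the rule for named genes were fixed. The rule took, in each of the 2 main comparisons, the 8 largest increases and 8 largest decreases among called probes with 1 symbol that went the same way in every pair, predicted genes aside. Where fewer than 4 passed in a direction, it added the 5 smallest p. Hdac3 was always named, with up to 3 members of each list by smallest p. In other comparisons it took the 4 largest changes each way, or the 2 smallest p each way where none passed. Lists covered the HDAC and NCoR/SMRT complex, DNA replication, G2 and mitosis, G1, p53 targets, DNA repair, apoptosis, sterol synthesis, fatty acid and LXR or PPAR targets, retinoid and thyroid targets, the circadian clock, interferon, inflammatory genes, fibroblast matrix, ER stress, oxidative stress, imprinted genes, growth factor response and markers of macrophages, endothelium, epithelium, muscle, neurons, cartilage and bone, adipocytes and red cells. They were tested with limma's camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, which asks whether the members move one way on balance and does not compare them with other genes. A set of sex-linked genes was read for detection only: Uty and Kdm5d were detected on 1 of 10 arrays and Eif2s3y on 0.

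Alternatives were the series table, scaling to the median or the 75th percentile, no floor, no detection filter, detection on all 10 arrays, an intensity trend, separate fits per system, no 72 h term, the block, each array left out, the mean of a gene's probes, a 2-fold minimum and the other list tests. Keeping spots with a high flag was chosen after seeing the data. Unchanged 4OHT groups were simulated 100 times (seed 1) against the shared vehicle arrays, with independent arrays and then with the correlations between arrays of 1 preparation. The overlap of calls expected for independent lists is the product of their sizes over the number of probes tested.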

Results

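Mouse embryonic fibroblasts (MEFs), connective tissue cells grown from mid-gestation embryos on a C57BL/6 background, were profiled with and without deletion of Hdac3, which encodes the catalytic subunit of the NCoR and SMRT corepressor complexes. The cells carried 1 floxed (Fl) Hdac3 allele, whose flanked part is removed by Cre recombinase. In the first system, Fl/- cells, whose other allele is null, and Fl/+ cells, whose other allele is wild type, were infected with an adenovirus carrying Cre (Ad-Cre), and each genotype gave 1 array at 64 h and 1 at 72 h. In the second system, Fl/- cells expressed Cre-ER, a fusion of Cre with the estrogen receptor that 4-hydroxytamoxifen (4OHT) activates. There, 2 MEF preparations were each treated with 1 micromolar 4OHT for 64 h or 72 h, or with ethanol vehicle for 64 h. The 10 arrays thus formed 5 groups of 2, and this number limits the precision of every comparison. Between 44.9% and 52.71% of the probes were detected per array, with median signals from 794.6 to 1088.76 intensity units. Correlations of log2 values across probes, which are not independent replicates, were 0.9896 to 0.9927 between the 2 arrays of a group.

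The first question was whether the targeted transcript was lost. Hdac3 was lower in Fl/- than in Fl/+ cells after Ad-Cre, with log2 intensities of 13.62 and 13.38 against 15.96 and 16.04. The fitted difference was -2.50 (SE 0.0897, 5.65-fold, adjusted p = 0.000145, lower at 2 of 2 times). In the Cre-ER cells, Hdac3 stood at 14.79 on both vehicle arrays, at 12.80 and 12.72 after 64 h of 4OHT and at 12.91 and 13.02 after 72 h. The mean of the 4OHT groups lay below vehicle by -1.93 (SE 0.0777, 3.81-fold, adjusted p = 0.0298, lower in 4 of 4 pairs of arrays of the same preparation). With the MEF preparation as a block, the same difference had adjusted p = 0.189, and 9 of 22 alternatives did not call it (adjusted p = 0.000884 to 0.189 over all). Whether the Hdac3 probe lies in the deleted part of the gene is not given in the sources used here.

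**Figure D1:**
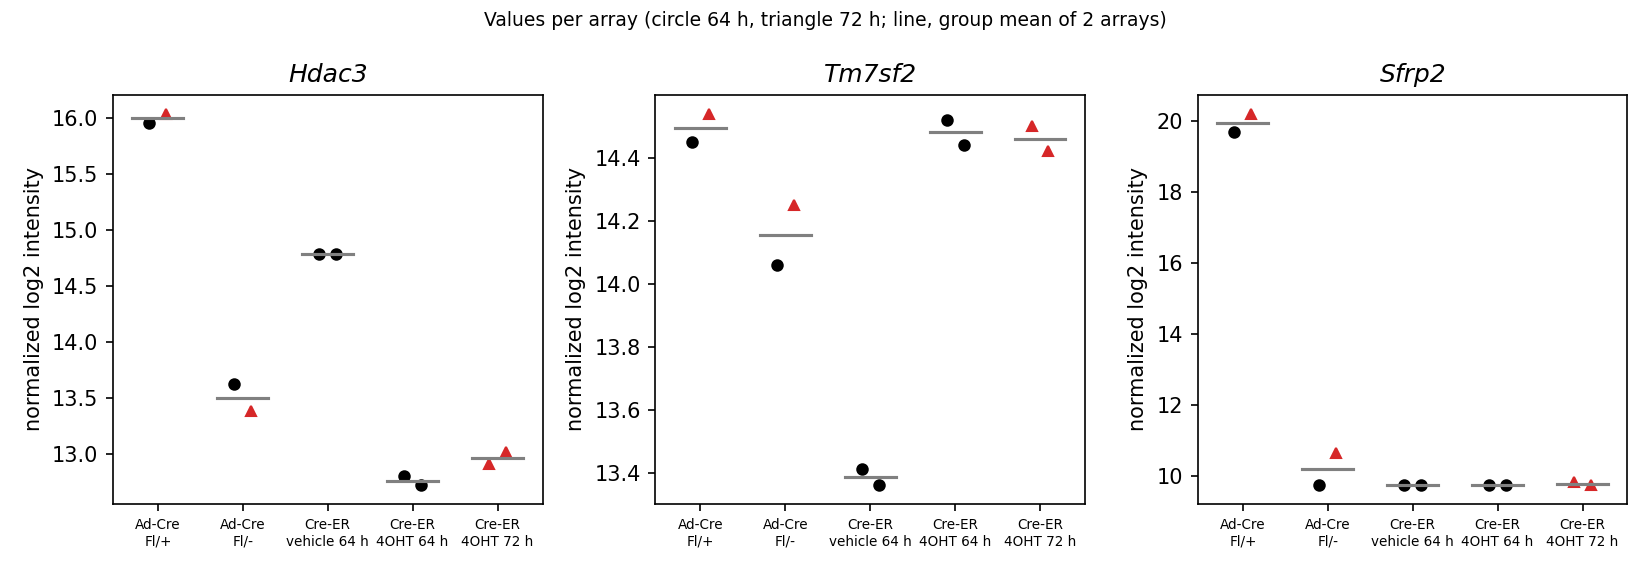
Normalized log2 intensity (vertical axis) of Hdac3, Tm7sf2 and Sfrp2 on each array, by group (horizontal axis), with circles for 64 h, triangles for 72 h and a line at the mean of the 2 arrays. Hdac3 lay at 15.96 and 16.04 in Ad-Cre Fl/+ cells, at 14.79 in both vehicle arrays and at or below 13.62 in the other groups.

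The Ad-Cre comparison asked which transcripts differed between cells that had lost Hdac3 and cells that kept a wild type allele. In Fl/- cells Sfrp2, a secreted Wnt antagonist, fell by 9.77 on the log2 scale, the chemokine Cxcl15 was at least 359-fold lower and not detected in Fl/- cells, and Lcn2, an iron carrier of the acute phase response, fell by 7.73 (SE 0.0515, 212-fold). Sned1, a matrix protein gene, fell by 7.05 (SE 0.125), Mest, a paternally expressed imprinted gene, fell by 6.96 (SE 0.145), and Galnt9, a glycosyltransferase gene, Clu, which encodes a secreted chaperone, and the enkephalin precursor gene Penk were at -6.75, -6.74 and -6.70. The named increases included Ifi27l2b at 6.28, Ankrd1, a YAP target and muscle stress gene, at 5.51 (SE 0.151, 45.6-fold), and the oxidized LDL receptor Olr1, which was at least 44.6-fold higher and not detected in Fl/+ cells. They also held 3 Hox genes, which mark positions along the body axis, namely Hoxc9 at 5.43, Hoxc8 at 5.04 and Hoxb6 at 4.78 (SE 0.105), the ribosomal protein paralog Rpl39l at 5.07 (SE 0.820) and the gut and neural peptide gene Cck at 4.86 (SE 0.471). Sfrp2 and Galnt9 were detected on 1 of 2 arrays in Fl/- cells, and Ifi27l2b, Hoxc9 and Hoxc8 on 1 of 2 in Fl/+ cells, so that their values are bounds on the difference and give no rank. These 16 genes had adjusted p from 1.34e-06 to 0.0103 and went the same way at both times, as the naming rule required. Their falls and rises are differences between the genotypes, not changes from an undeleted state. For all 16, the undeleted Fl/- vehicle cells of the other system lay nearer to Fl/- than to Fl/+ cells. Mest stood at 12.53 in vehicle, 12.69 in Fl/- and 19.66 in Fl/+ cells, Clu at 12.87, 12.83 and 19.57, and Hoxc9 at 15.5, 15.65 and 10.22. Rpl39l did not pass without any 1 of the 4 Ad-Cre arrays (adjusted p = 0.079 to 0.102).

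Across the array, 6267 of 19297 tested probes (32.5%) differed between the genotypes, 3292 higher and 2975 lower in Fl/- cells, and 2259 of them by at least 2-fold. Scaling the arrays to a common median in place of quantile normalization gave 2146 higher and 3830 lower, so the higher share was 35.9% against 52.5%. Leaving out 1 Ad-Cre array leaves a group of 1 that is assumed to vary like the others. The count was then 3793 without the Fl/- 64 h array, 3069 without the Fl/- 72 h array, 3530 without the Fl/+ 64 h array and 2793 without the Fl/+ 72 h array.

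Genes of the interferon response, the antiviral program of most cells, were lower in Fl/- cells. Of 24 measured members, 22 fell and none rose, both over all genes and adjusted over the list alone, and the list median was -1.73. Oasl1, Mx2 and Oasl2, antiviral effectors, fell, with values of -1.93, -2.39 and -3.58 (SE 0.0324, 0.0503 and 0.0899). These SEs are too small, as all Cre-ER arrays lay at the floor for these genes and added no spread. Between the 2 arrays of a genotype, Oasl1 had an SD of 0.45 in Fl/- and 0.471 in Fl/+ cells, part of which the 72 h term took up. Calls of other members at the floor in Cre-ER arrays share this limit. The list ranked below other genes (camera adjusted p = 9.3e-12; adjusted p = 0.367 with an estimated correlation). Inflammatory cytokines and NF-kB targets had 9 of 22 members lower and 2 higher, and 10 lower and 2 higher adjusted over the list alone, with the neutrophil chemokine Cxcl1 down by -3.46 and the alarmin Il33 by -1.95 (median -0.62, camera adjusted p = 0.0279; adjusted p = 0.407 with an estimated correlation). Markers of macrophages, a cell type that MEF cultures can hold, went the other way: 4 of 8 rose, 6 adjusted over the list alone, among them Cd14 by 1.29 and the complement gene C1qa by 1.73 (median 0.99, camera adjusted p = 0.0428; adjusted p = 0.829 with an estimated correlation). Without any 1 of the 4 Ad-Cre arrays the macrophage list had camera adjusted p from 0.0681 to 0.155, and without either 4OHT array of 72 h 0.0587 and 0.0582. Without the Fl/- 72 h array the inflammatory list had 0.0587.

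Genes of G2 and mitosis passed camera downward in the main model, a call that 5 of 23 alternatives ended. Of 28 members, 5 fell and none rose, 3 adjusted over the list alone, with the phosphatase gene Cdc25b down by -0.89 (SE 0.1) and the spindle gene Nusap1 by -1.34 (SE 0.2). The median was -0.27 (camera adjusted p = 0.0279; adjusted p = 0.829 with an estimated correlation). Without the Fl/- 72 h array, or without the Fl/+ 72 h array, camera gave adjusted p = 0.323 and 0.217, and with no 72 h term 0.104, while fry gave 0.111. The DNA replication list, which bears on entry into and passage through S phase, had 7 of 40 members higher and 3 lower (6 and 1 adjusted over the list alone), with the primase subunit gene Prim2 up by 0.61 and the origin recognition gene Orc2 by 0.51, a median of 0.04 and camera adjusted p = 0.849. Among 29 DNA repair and checkpoint genes, 3 rose and 5 fell (3 and 5 adjusted over the list alone). Prkdc, the catalytic subunit of DNA-dependent protein kinase, was at least 2.10-fold lower and not detected in Fl/- cells, the checkpoint kinase gene Atm rose by 0.60, and camera gave adjusted p = 0.66. Of 25 p53 targets, 6 rose and 7 fell (6 and 10 adjusted over the list alone), with values from -2.11 to 1.88 (camera adjusted p = 0.861). Named by smallest p were the polo-like kinase genes Plk3 and Plk2, up by 1.85 and 1.88. Of 19 G1 regulators, 4 rose and 4 fell, as many adjusted over the list alone, with E2f6 up by 1.22 and Myc by 2.21 (camera adjusted p = 0.861). Apoptosis regulators had 5 of 19 higher and 3 lower, as many adjusted over the list alone (camera adjusted p = 0.597). The median and mean differed in sign for the p53 targets (-0.12 and 0.04) and the G1 regulators (-0.0076 and 0.17).

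The adipocyte marker list was lower in Fl/- cells, while lipid genes changed in both directions. Of its 4 measured members, 3 fell, as many adjusted over the list alone, with the transcription factor genes Cebpb, down by -0.87, and Cebpd, down by -1.63 (median -0.77, camera adjusted p = 0.0337; adjusted p = 0.407 with an estimated correlation and 0.0621 with no floor). Both also stood high in vehicle cells, at 17.8 and 15.48, so their fall need not mean fewer adipocytes. In the list of fatty acid genes and LXR and PPAR targets, 6 of 21 rose and 8 fell (6 and 9 adjusted over the list alone), with the nuclear receptor gene Pparg down by -4.35 (SE 0.197) and its target Fabp4, a fatty acid binding protein, by -4.21 (SE 0.221), while camera gave adjusted p = 0.569. Sterol synthesis genes had 6 of 15 members higher and 1 lower (8 and 1 adjusted over the list alone), with the sterol carrier gene Stard4 up by 1.70 and Hsd17b7, of the cholesterol pathway, by 1.41. The list median of 0.60 did not pass (camera adjusted p = 0.0658), while 7 of 23 alternatives called it (0.013 to 0.829 over all). In the HDAC and NCoR/SMRT complex list, 5 of 13 members fell, Hdac3 included, and 1 rose, as many adjusted over the list alone. Hdac5 was down by -0.95 and the complex subunit gene Tbl1x up by 0.64 (camera adjusted p = 0.153).

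The other lists did not pass camera between the Ad-Cre genotypes. Members rose and fell as follows, over all genes and then adjusted over the list alone: 2 and 4 of 11 retinoid and thyroid receptor targets (2 and 4), 2 and 5 of 11 circadian clock genes (2 and 5), 8 and 8 of 35 fibroblast matrix and contractile genes (9 and 9, with a median of 0.12 and a mean of -0.09), 7 and 1 of 22 ER stress and ATF4 targets (7 and 1), and 6 and 4 of 22 oxidative stress and xenobiotic genes (8 and 4). For imprinted growth genes it was 2 and 2 of 12 (2 and 2), and for growth factor response genes 11 and 7 of 32 (12 and 9). Of the markers of other cell types, 0 of 5 endothelial and 0 of 4 erythroid markers passed either way. Of 6 epithelial markers 1 rose (2 adjusted over the list alone), of 10 skeletal muscle markers 1 rose (1), of 6 neural markers 2 fell (2), and of 7 cartilage and bone markers 4 fell (4, with 1 higher). Camera adjusted p for these lists ran from 0.146 for the cartilage and bone markers to 0.967 for the erythroid markers. With an estimated correlation, no list of either main comparison passed.

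**Figure D2:**
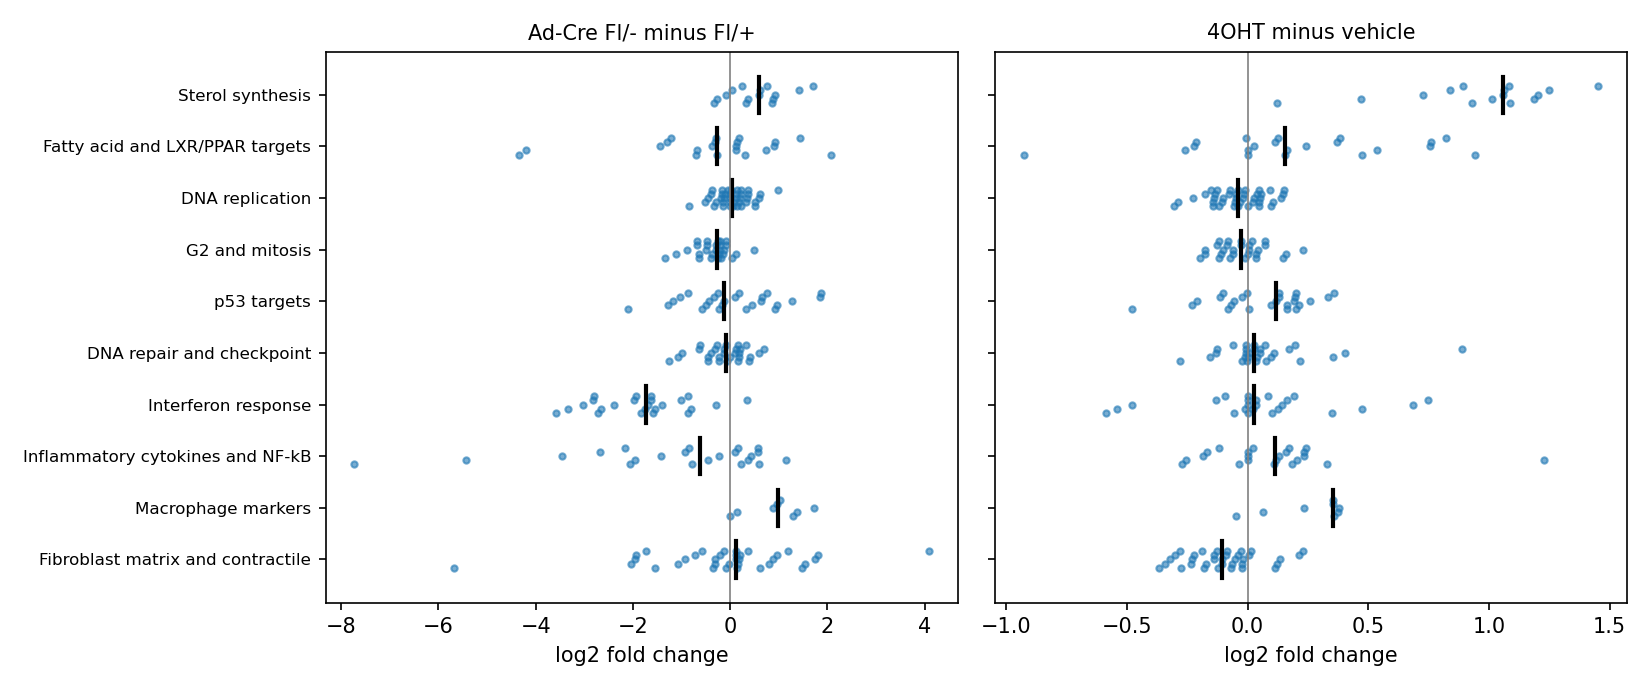
Log2 fold changes (horizontal axis) of the measured members of 10 gene lists (vertical axis) for Ad-Cre Fl/- minus Fl/+ cells and for 4OHT minus vehicle, with 1 point per gene and a bar at the list median; the 2 horizontal axes have different scales. The interferon list has its median at -1.73 in the Ad-Cre comparison and 0.03 under 4OHT, and the sterol synthesis list has it at 0.60 and 1.06.

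The Cre-ER system compared parallel cultures of 1 genotype given 4OHT or vehicle, so that the drug, active Cre-ER and the deletion came together. Besides Hdac3, 1 named gene passed the test: Tm7sf2, a sterol reductase of the last part of cholesterol synthesis, rose by 1.08 (SE 0.0472, 2.12-fold, adjusted p = 0.0298, higher in 4 of 4 pairs). The next increases in order of p did not pass, and they also belong to lipid synthesis: the desaturase gene Fads2 at 0.75 (adjusted p = 0.11), the isoprenoid enzyme genes Idi1 at 1.45 (0.147) and Mvd at 1.09 (0.158), and the sterol enzyme genes Cyp51 at 1.19 (0.163) and Hsd17b7 at 0.93 (0.163). On the lower side, Zfp599 (adjusted p = 0.0862) did not pass either, with all 4OHT arrays at the floor, so that its value of -1.01 bounds the difference. Cd79a, Zfp526, Krtap13-1 and Nptx1, not detected after 4OHT, were at least 1.41-fold, 1.46-fold, 1.36-fold and 2.35-fold lower and did not pass (adjusted p = 0.11 to 0.163). In all, 4 of 19322 probes passed by limma, 1 higher and 3 lower, the other lower ones being unnamed probes at -0.67 and -0.58, while 1623 had an unadjusted p under 0.05 where chance gives 966. With the MEF preparation as a block the count was 0, with adjusted p = 0.18 for Tm7sf2, which 12 of 22 alternatives did not call (adjusted p = 0.0099 to 0.206 over all). On simulated data with the same layout, the fit found 74% of probes changed 2-fold and 95% of those changed 4-fold. Those probes lay well above the floor and the simulated arrays were independent. The shares therefore do not speak for dim probes or for arrays tied by preparation.

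Sterol synthesis genes stood higher after 4OHT as a group. All 15 measured members had positive values, with a median of 1.06. Only Tm7sf2 passed over all genes, and 14 passed adjusted over the list alone. The list ranked above other genes by camera (adjusted p = 1.08e-25; adjusted p = 0.197 with an estimated correlation) and its members moved on balance upward by fry (adjusted p = 0.00608), which does not compare them with other genes. With the preparation as a block, camera gave adjusted p = 2.49e-22. In the list of fatty acid genes and LXR and PPAR targets, 15 of 21 members had positive values (median 0.15), 0 passed over all genes, and 5 higher and 1 lower passed adjusted over the list alone, with the fatty acid synthase gene Fasn at 0.54 beside Fads2 (camera adjusted p = 0.00896; adjusted p = 0.644 with an estimated correlation and 0.11 by fry).

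Matrix and contractile genes of fibroblasts had negative values in 28 of 35 members after 4OHT, with the smooth muscle gene Cnn1 at -0.34 and the collagen gene Col4a2 at -0.23 (median -0.11, camera adjusted p = 0.0263; adjusted p = 0.644 with an estimated correlation). Macrophage markers were positive in 7 of 8, with Cd14 at 0.36 (median 0.36, camera adjusted p = 0.0311; adjusted p = 0.644 with an estimated correlation). No member of these lists passed over all genes or adjusted over the list alone. Neither call was firm: 7 of 23 alternatives ended the first (adjusted p = 0.0668 to 0.644), among them both other scalings, and 10 of 23 the other (0.0706 to 0.644), among them leaving out any 1 of the 4 Ad-Cre arrays or the second vehicle array (0.478). The DNA replication list had a median of -0.04 (camera adjusted p = 0.394), with the helicase subunit gene Mcm6 at -0.29 and the origin gene Orc1 at -0.30, neither of which passed. p53 targets had a median of 0.12 (camera adjusted p = 0.0533), with Gtse1 at 0.33 and the apoptosis gene Bbc3 at 0.21, and the DNA repair and checkpoint list one of 0.03 (camera adjusted p = 0.366), with the excision repair gene Xpa at 0.36. The interferon list, with a median of 0.03, had 1 member higher and 1 lower adjusted over the list alone (camera adjusted p = 0.649). Camera adjusted p of all lists that did not pass ran from 0.0533 to 0.99.

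Taken by time, 4OHT left Hdac3 below vehicle by -2.03 at 64 h (SE 0.0897, adjusted p = 0.0475) and by -1.83 at 72 h (SE 0.0897, adjusted p = 0.04), and Tm7sf2 above it by 1.09 and 1.08 (adjusted p = 0.0475 and 0.04). The 64 h comparison called 2 probes higher and 3 lower, and the 72 h one, whose vehicle was taken 8 h earlier, 3 higher and 4 lower, with 0 calls at either time when the preparation was a block. Both use the same 2 vehicle arrays, which alone ties their fold changes together: the correlation across probes was 0.532, against a mean of 0.501 (highest 0.53) in 100 simulations of unchanged groups whose arrays were independent. With arrays of 1 preparation correlated across groups as measured, a simulation chosen after the result was seen, the mean was 0.55 (0.519 to 0.575), a range that holds the observed value. The covariance was 0.0361 against 0.0303 and 0.0271 simulated without and with the preparations, a difference of 0.00586 and 0.00906. Of the calls, 1 was higher and 3 were lower at both times, where independent lists would share 0.000311 and 0.000621, and with 2 vehicle arrays part of this excess may come from the shared controls.

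The time comparisons asked what changed from 64 h to 72 h. In the 4OHT groups Hdac3 differed by 0.21 (adjusted p = 0.695). Mitotic genes were higher at 72 h as a group: 24 of 28 G2 and mitosis genes had positive values after 4OHT (median 0.24, camera adjusted p = 2.35e-06; adjusted p = 0.835 with an estimated correlation) and 27 of 28 after Ad-Cre (median 0.56, camera adjusted p = 2.81e-17; adjusted p = 0.429 with an estimated correlation). None of these genes passed over all genes, and 7 passed adjusted over the list alone after Ad-Cre and 0 after 4OHT. Against vehicle, the list lay lower after 64 h of 4OHT (median -0.14, camera adjusted p = 0.00662; adjusted p = 0.957 with an estimated correlation) and did not pass after 72 h (0.13, 0.0874). By these medians, part of the first difference may be a lower level at 64 h, which is not firmly shown. By fry the time differences had adjusted p = 0.581 and 0.195. Without the second 4OHT array at 64 h the first median was 0.11 (camera adjusted p = 0.276). Among the 4OHT arrays, limma called 0 probes, with 1505 at an unadjusted p under 0.05 where chance gives 966. The nearest named genes were Zfp715, at least 1.70-fold higher and not detected at 64 h (adjusted p = 0.0922), Nxnl1, at least 1.58-fold lower and not detected at 72 h (0.156), and Ldlrad3 at -0.69 (0.156). Mlph (0.111), not detected at 64 h, rests on 1 array at 72 h, its other spot being left out, and was at least 1.85-fold higher, or 7.86-fold with that spot kept. Among the Ad-Cre arrays, 8 probes were higher and 1 lower at 72 h. The tight junction gene Cldn10, at the floor on both 64 h arrays and detected on 1 array of each time, was at least 1.89-fold higher, Il33 rose by 0.87 (SE 0.0435), the histone acetyltransferase gene Kat7 was at least 1.63-fold and the dipeptidase gene Cndp1 at least 1.60-fold higher, both not detected at 64 h. With the preparation of the Cre-ER arrays as a block, this count of 9 was 0. For the named genes among them all Cre-ER arrays lay at the floor, so their SEs are too small. Growth factor response genes (median 0.05) and macrophage markers (0.35) also passed camera in the 4OHT arrays (adjusted p = 0.0316 for both), and sterol synthesis (0.40, adjusted p = 1.21e-07), interferon (0.12, 0.00262), fatty acid (0.16, 0.00708) and DNA replication genes (0.12, 0.0316) in the Ad-Cre arrays. None of these held with an estimated correlation (adjusted p = 0.429 to 0.835).

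**Figure D3:**
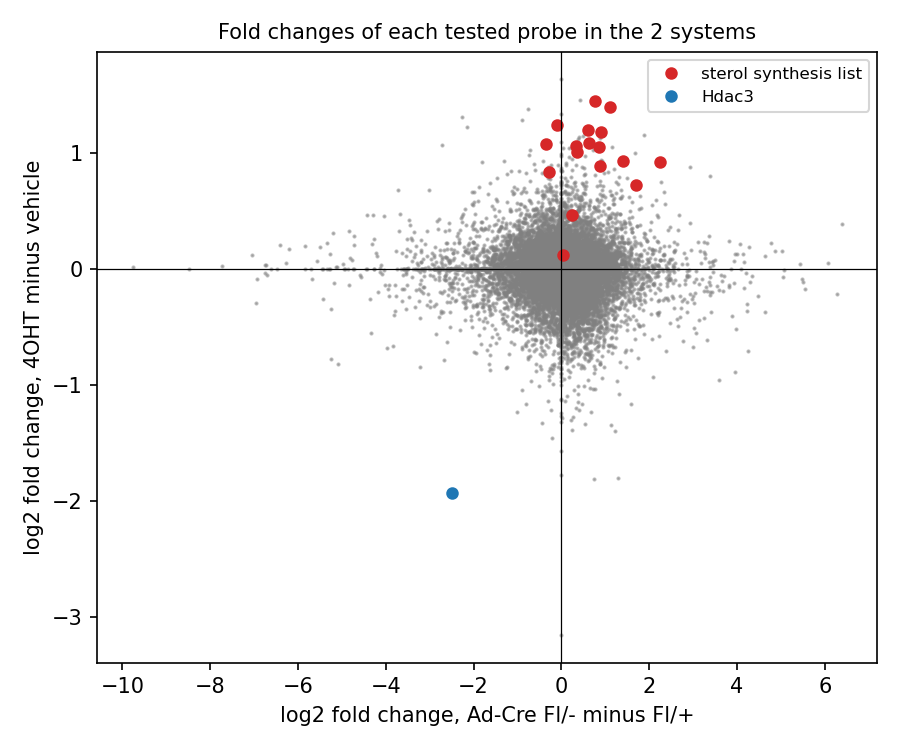
Log2 fold change under 4OHT (vertical axis) against that between the Ad-Cre genotypes (horizontal axis), with 1 grey point per tested probe, probes of sterol synthesis genes in red and Hdac3 in blue. Hdac3 is low on both axes, at -2.50 and -1.93, and the correlation across probes is -0.035.

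Set side by side, the 2 systems shared no probe called in the same direction beside Hdac3. As the 4OHT comparison called only 4 probes, little overlap was possible. Of the lists, macrophage markers passed camera upward in both, though neither call held without any 1 of the 4 Ad-Cre arrays or with an estimated correlation (adjusted p = 0.829 and 0.644). Sterol synthesis genes had positive medians in both, and their difference between the systems did not pass (median -0.47, camera adjusted p = 0.0649). Hdac3 was the 1 transcript called lower in both, where independent lists would share 0.463, and 0 were called higher in both, where they would share 0.171. Hdac3 is the deleted gene, so its place in both lists follows from the design and says nothing on shared effects. Tm7sf2 was called in opposite directions, at -0.34 between the Ad-Cre genotypes. The Hdac3 change under 4OHT was 77.3% of that after Ad-Cre on the log2 scale. The difference of -0.57 (SE 0.119, adjusted p = 0.0294) had adjusted p = 0.0513 with the preparation as a block. Of 21 alternatives, 13 did not call it (0.0186 to 0.144 over all). The smaller change does not mean that more Hdac3 was left after 4OHT. Hdac3 averaged 12.76 at 64 h and 12.96 at 72 h of 4OHT, both below its mean in Ad-Cre Fl/- cells. The groups compared against also differed, with vehicle at 14.79 and Fl/+ at 16. The fold changes had r = -0.035 and rho = -0.051 across 19296 probes, and 48.2% of 5938 Ad-Cre calls had the same sign under 4OHT. The log2 changes had an SD of 0.228 under 4OHT and 0.831 after Ad-Cre. Measurement spread in the small 4OHT changes weakens such a correlation. In the direct test of the difference, 4453 probes passed, led by the genes that led the Ad-Cre comparison: Ifi27l2b at 6.49, Ankrd1 at 5.62, Olr1 at 5.56 and Hoxc9 at 5.39, and Sfrp2 at -9.79, Cxcl15 at -8.49, Lcn2 at -7.75 and Sned1 at -7.17. Olr1 did not pass without either Ad-Cre array of 72 h (adjusted p = 0.0601 and 0.0615). Where all arrays of a group lay at the floor, such a difference rests on the floor. The interferon list differed by a median of -1.89, with 20 of 24 members lower, 21 adjusted over the list alone (camera adjusted p = 1.84e-11; adjusted p = 0.353 with an estimated correlation).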

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

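All the tests of the 3 patterns weighed here were chosen only after the result was seen, except that of 1 stray array for the sterol genes.

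The difference between the Ad-Cre genotypes differed from the 4OHT change on 4453 probes, by limma's test of the difference itself, and of 82 named genes, most of them picked for large changes or small p in its parts, 67 passed it. Where all arrays of a group lay at the floor, as for Cxcl15, Olr1, Tbx5 and others below, the difference rests on the floor. On the log2 scale, the difference was 6.49 for Ifi27l2b, 5.62 for Ankrd1, 5.56 for Olr1, 5.08 for Rpl39l and 4.70 for Cck. It was -9.79 for Sfrp2, -8.49 for Cxcl15, -7.75 for Lcn2, -7.17 for Sned1, -6.67 for Mest, -6.79 for Galnt9, -6.78 for Clu and -6.65 for Penk, and -0.57 for Hdac3 itself. Over 6267 Ad-Cre calls, loss of Hdac3 as the whole cause would need most to move the same way under 4OHT. That need assumes that Hdac3 protein was lost for as long and as fully in both systems, and only RNA was measured. Of the 5414 calls off the floor in the Cre-ER arrays, 48.1% moved the same way (43.9% to 53.4% over the 4 pairs of 4OHT and vehicle arrays). Under that assumption, the share argues against loss of Hdac3 as the whole cause. A like share, 48.2% of 5938 calls, had already been seen, so the check is not independent of the result that prompted it. A uniform difference in brightness, or one in detection, between arrays is argued against too as the whole cause, since at least 31% of tested probes were called under the other scalings and on probes detected on all arrays. Those scalings multiply each array by 1 factor, so they cannot test a brightness difference that varies with intensity. The scaling did shape the direction of calls, with 35.9% higher under median scaling against 52.5%. Among what stays open is that the Fl/+ culture may have had another make-up or origin than the others: on 77% of the calls Fl/+ lay farther than Fl/- from the undeleted vehicle arrays (76.1% and 77.3% with either array). These distances do not single it out, because vehicle and Fl/- cells also share the null allele that Fl/+ cells lack. The culture explanation is a hypothesis found and tested on the same data, and as each genotype may be a single culture, genotype and culture were not separated by the design.

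Hox genes also differed between the systems, with Hoxc9 at 5.39, Hoxc8 at 5.11 and Hoxb6 at 4.55. So did genes of limb position read after their values were seen, Hoxd10 at -4.36 and Tbx5 at -2.18. Of 25 measured Hox genes, 12 were called higher and 5 lower in Ad-Cre Fl/- than Fl/+ cells. Under the same assumption on Hdac3 protein, loss of Hdac3 is argued against as the cause. The 15 called Hox genes detected in the vehicle arrays had a median 4OHT change of 0.07 in the Ad-Cre direction (0.0703, and 0.0371 to 0.187 over the 4 pairs), against 3.27 after Ad-Cre. Cultures from other positions of the embryo are a candidate explanation: Fl/+ lay farther than Fl/- from vehicle on 100% of the called genes (17 of 17), by a median of 3.51 against 0.47, and genes went both ways. Vehicle and Fl/- cells also share the null allele that Fl/+ cells lack, so these distances do not separate position from genotype. No label gives the part of the embryo, and the position explanation was found and tested on the same data, so it stays open.

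The sterol gene Tm7sf2 differed by -1.43 between the systems and the desaturase gene Fads2 by -0.45, with the 4OHT change the higher one. The rise of the sterol list under 4OHT (median 1.06) stayed under the other scalings, with a lowest median of 0.98 (0.983). With no floor it was 1.06 again, a check of little force because these genes lay far above the floor. It was not due to 1 stray array, as the lowest median over the 4 pairs was 0.95 (0.946). Whether 4OHT itself, apart from Hdac3, was the cause cannot be told apart from loss of Hdac3, since all 4OHT arrays had both and no array held 4OHT without Cre-ER. The Ad-Cre comparison, which had no 4OHT, does not settle it: the list median there was 0.60 (0.597), with camera adjusted p = 0.0658 and fry adjusted p = 0.013, and 7 of 23 alternatives called it, while camera with an estimated correlation did not (0.829), so a rise without 4OHT is neither shown nor excluded. Both may therefore stand as hypotheses, and tamoxifen derivatives are known to bind enzymes of sterol synthesis.

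The remaining differences between the systems are given as values. For immune genes they were -1.93 for Oasl1, -2.39 for Mx2, -3.58 for Oasl2, -3.61 for Cxcl1, -1.95 for Il33, 0.93 for Cd14 and 1.35 for C1qa. For genes of the cell cycle, DNA replication and repair they were -1.25 for Nusap1, -0.71 for Cdc25b, 0.64 for Prim2, 0.61 for Orc2, 0.81 for Orc1, 1.30 for E2f6, 2.23 for Myc, 1.92 for Plk3, 1.71 for Plk2, -1.18 for Prkdc, 0.66 for Atm, -0.70 for Bbc3 and -0.63 for Xpa. Genes of the lipid and adipocyte lists gave -1.01 for Cebpb, -1.56 for Cebpd, -4.09 for Pparg, -4.32 for Fabp4 and 0.97 for Stard4. Matrix and contractile genes gave 0.96 for Cnn1, 1.20 for Col4a2, -5.59 for Lum, -3.34 for Comp, -1.60 for Acan and 2.13 for Col2a1. Clock genes gave -1.82 for Dbp, 1.69 for Arntl and -0.96 for Tef, and ATF4 targets 1.05 for Asns, 1.12 for Psat1 and 1.11 for Chac1. The others were -1.16 for Hdac5, 1.39 for Zfp599, 0.53 for Cd79a, 0.40 for Zfp526, 0.48 for Krtap13-1, 0.25 for Kat7, -0.44 for Mlph, 1.11 for Nxnl1 and -0.73 for Ldlrad3.

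By camera, 5 lists differed between the systems: interferon (median -1.89), inflammatory genes (-0.74, adjusted p = 0.0113), adipocyte markers (-0.78, 0.0404), fatty acid and LXR or PPAR targets (-0.45, 0.0347) and G2 and mitosis (-0.32, 0.0497). Between 72 h and 64 h of 4OHT, G2 and mitosis genes differed by a median of 0.24, growth factor response genes by 0.05 and macrophage markers by 0.35. None of these held with an estimated correlation (adjusted p = 0.353 to 0.874).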

How the results depend on the processing

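Keeping spots with a high flag was the 1 alternative chosen only after the result was seen. A block of scan date or slide was not run, as no such field was found in the deposited tables used here. No value past the threshold changed sign. Hdac3 between 72 h and 64 h of Ad-Cre, which was not called, did so without either Fl/- array (-0.24 to 0.08 over all). The balance of Ad-Cre calls also turned, from 3292 higher and 2975 lower to 2146 and 3830 with median scaling, 1446 and 1623 without Fl/- 72 h, 1394 and 1399 without Fl/+ 72 h, and 1045 and 1214 with a 2-fold minimum. That of the difference between systems, 2312 and 2141, was 1753 and 2085 with median scaling, and also turned with no filter, a 2-fold minimum and without either Ad-Cre 72 h array. Of 365 recomputed values of the 17 genes named among these calls, 361 stayed past the threshold, the other 4 being Rpl39l without each Ad-Cre array in turn, while of 132 for the 4OHT genes past the threshold 57 did, and of 182 for the 9 genes named for the difference between systems 167 (the rest being 13 of Hdac3 and 2 of Olr1). The correlation between the systems stayed between -0.0626 and 0.0003. Where a count moved, the cause was not tested, except where fewer arrays, fewer probes or a size minimum set it. A 2-fold minimum left 2259 Ad-Cre calls, 2 for 4OHT, 2 at 64 h, 4 at 72 h, 1 for Ad-Cre 72 h against 64 h and 2140 for the difference between systems. With an estimated correlation, 0 lists passed against 9 (interferon after Ad-Cre -1.73, adjusted p = 0.367; sterol synthesis after 4OHT 1.06, adjusted p = 0.197), and fry called 17. The calls for 4OHT, 64 h, 72 h and 72 h against 64 h, 4, 5, 7 and 0 in the main model, depended on most settings. Median scaling gave 0, 0, 2 and 1 and shifted the median of all probes by -0.12 at 72 h, and 75th percentile scaling gave 1, 1 and 0 for the first 3. No floor gave 0, 0 and 0, and no detection filter 28, 17, 27 and 35. Detection on all 10 arrays gave 18, 2 and 13, among them Fads2, Idi1, Mvd and Cyp51. An intensity trend gave 11 for 4OHT and 6 for 72 h against 64 h, no 72 h term 13, 17 at 72 h and 7 for 72 h against 64 h, the authors' normalized values 3 for the last, separate fits 0, 0 and 0, and keeping high flags 0 at 64 h. With the preparation as replicate block, 4OHT, 64 h and 72 h calls were 0, as were the 9 for Ad-Cre 72 h against 64 h, and the Hdac3 difference between systems had adjusted p = 0.0513; it ended no other call in the results named here. Those 9 were also 0 with the authors' normalized values, no floor, detection on all arrays and separate fits, 20 with a trend and 50 with no filter. Separate fits gave 3683 Ad-Cre calls, and no filter 2954 for the difference between systems. Without 1 array in turn, a group of 1 being assumed to vary like the others, Ad-Cre calls ran from 2793 (without Fl/+ 72 h) to 6131, the difference between systems from 2104 (without Fl/+ 72 h) to 4208, 4OHT from 0 to 47 (without the first vehicle array, and 39 without the second), 64 h from 0 to 66 (without the second 4OHT array of 64 h), 72 h from 0 to 47 (without either 4OHT array of 72 h), 72 h against 64 h from 0 to 64 (without the second 4OHT array of 64 h), and Ad-Cre 72 h against 64 h from 0 (without any Cre-ER array) to 555 (without Fl/- 64 h). Signal over background limits what can be seen: 6466 of 19323 tested probes lay at the floor on at least 1 array.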

Other observations

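The clock and amino acid response genes below were named by the fixed rule, while Nr1d1, Nr1d2, Col2a1, Pitx1, Tbx5, Hoxd10 and Hoxa11 were chosen only after their values were seen. Hoxd10 and Hoxa11 are among the Hox genes weighed earlier, and the other values were tested against no explanation.

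Among the clock genes, whose list did not pass camera between the Ad-Cre genotypes (adjusted p = 0.597), the 3 of smallest p went as follows. Arntl, which encodes the activator BMAL1, rose by 1.81 in Fl/- cells (SE 0.119, adjusted p = 0.000802), while Dbp and Tef, output genes that peak when Arntl is low, fell by 1.89 (SE 0.0867, adjusted p = 0.000305) and fell by 0.93 (SE 0.117, adjusted p = 0.00493). Nr1d1, which also peaks when Arntl is low, stood at 0.29 (adjusted p = 0.279). The related gene Nr1d2 averaged 12.84 in Fl/- and 13.53 in Fl/+ cells. Of the 11 clock genes measured, 2 rose and 5 fell. Under 4OHT Arntl, Dbp and Tef stood at 0.12, -0.07 and 0.03, none of which passed. Asns, Psat1 and Chac1, targets of the amino acid stress factor ATF4, rose by 1.15, 1.22 and 1.37 between the Ad-Cre genotypes (adjusted p = 0.00118, 0.00208 and 0.00263) and stood at 0.11, 0.10 and 0.27 under 4OHT without passing; the ER stress and ATF4 list did not pass camera (adjusted p = 0.246). Of matrix genes, Comp was at least 10.1-fold lower and not detected in Fl/- cells, Acan, detected on 1 of 2 arrays there, fell by 1.52, a bound on the difference, and the proteoglycan gene Lum fell by 5.67 (SE 0.344), while the cartilage collagen gene Col2a1 stood at 1.33 (adjusted p = 0.0642). Fbln2 and Col4a2 were higher in Fl/- cells, at 20.78 against 18.97 and 16.33 against 15.36. The fibroblast matrix and contractile list had 8 of 35 members higher and 8 lower. The cartilage and bone list did not pass camera (adjusted p = 0.146).

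The interferon list had its highest level in the Ad-Cre Fl/+ cells and its lowest in the uninfected cells. The median log2 level of its 24 measured members was 14.72 in Fl/+ and 12.12 in Fl/- cells after Ad-Cre, and 10.17 in vehicle, with 23, 22 and 11 members detected on both arrays of the group. The systems differ in adenovirus and cell stock alike, and no array held infected cells without Cre. Oasl2 stood at 17.00 in Fl/+ and 13.43 in Fl/- cells and at the floor of 9.74 in vehicle.

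Genes of limb identity were not tested as a group, and 4 are given here. Pitx1, a hindlimb factor, averaged 16.14 in Ad-Cre Fl/- cells, was not detected in Fl/+ cells, and was detected on 1 of the 2 arrays in each Cre-ER group (SD 3.22, 2.84 and 2.56), so that its difference between the Ad-Cre genotypes, 6.39 against the floor and thus a lower bound, had adjusted p = 0.0939. Tbx5, a forelimb factor, was detected on both Fl/+ arrays, at 11.92, and not in Fl/- cells (-2.18 to the floor, a bound on the difference, adjusted p = 1.01e-05). The distal limb genes Hoxd10 and Hoxa11 were lower in Fl/- cells by -4.22 and -3.27 (adjusted p = 0.0125 and 0.0254).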
